A study of Mus musculus with 8 samples.

How the data were processed

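RNA-seq was done on the proximal colon of 8 gnotobiotic NMRI mice, which are animals raised without microbes and then given a defined set of bacteria. Per the labels, 4 mice (group NoDp, replicates 1 to 4) received 8 human gut species, and 4 mice (group Dp, replicates 5 to 8) received those 8 species plus Desulfovibrio piger, a bacterium that reduces sulfate to hydrogen sulfide. The mice were 7 to 8 weeks old, ate a high-fat, high-sugar diet with 3% chondroitin sulfate, and were killed 2 weeks after colonization. Per the labels' protocols, RNA was extracted with a phenol reagent and a column with DNase treatment, mRNA was enriched on poly(A) beads, and libraries were made with a modified Illumina preparation. Strand was not stated, so antisense or overlapping genes cannot be told apart.

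The deposited values are raw counts of reads per Ensembl gene, 1 table per mouse, per the file headers. Per the submitters' processing notes, TopHat and Bowtie were used; their versions and roles, the read counter, the annotation release and the genome build are not given in the sources used here, and no coordinates are therefore reported. How reads shared by near-identical genes were counted is likewise not given, so values for immunoglobulin segments and for the Gsdmc genes are uncertain. Each table held 25077 genes and 2 closing lines without a gene name. The closing lines were left out; the count in the first equalled 0.00255% to 0.00338% of a library. A gene name table gave symbols for 23452 of the IDs, and 1625 kept their ID.

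Counts per library ranged from 6.004 to 25.2 M reads (M, megareads). Genes were kept by the filterByExpr function of edgeR 4.0.16 (R 4.3.3), which left 18115 genes, and were scaled by TMM. The main test was edgeR's quasi-likelihood test of Dp against NoDp with no covariate, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are Dp minus NoDp on the log2 scale, given with their standard error (SE). Levels are CPM (reads scaled to a common library size with TMM), given as mean ± SD over 4 mice. The biological coefficient of variation was 32.1%. The median SE was 0.25 log2, and the 95% interval of a gene's fold change reached a median of 0.57 log2 to either side. The median fold change of all genes was 0.02, and 0.02, 0.05 and 0.00 with median-ratio, upper-quartile and library-size scaling. The p-values treat the mice as independent; cages were not given.

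Before the data were examined, 43 gene lists were fixed. They covered sulfide handling, epithelial function, immunity, markers of cell types and signs of dissection or RNA quality. The 42 lists with 5 or more tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists, and also with an estimated correlation and with fry. The sex-linked list had fewer members and is not analysed here. Members were adjusted over all genes and over the list alone. For each mouse, a list score was the mean log2 CPM of its members with a prior count of 2, compared by an exact two-sided permutation test. The 70 assignments of 4 against 4 mice allow no p below 0.0286.

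Named genes followed a rule fixed in advance. It took up to 12 genes per direction that passed with groups that did not overlap and a mean of at least 1 CPM or, with none passing, the 5 of lowest p in each direction, named as not passing. It added 20 anchor genes and up to 4 members of lowest p from each list described. The number taken per list, from 1 to 4, was not part of that rule and depended partly on which lists were called. Gsdmc, Gsdmc2, Gsdmc3, Gsdmc4, Igkc and Pnlip were named after their values were seen. The cell type lists follow tissue composition and do not name cells.

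Alternatives fixed in advance were median-ratio, upper-quartile and library-size scaling, DESeq2 1.42.0, limma-voom with quality weights, no filter, a filter of 1 CPM in 4 libraries, the smooth muscle score or 1 surrogate variable (sva 3.50.0) as a covariate, robust dispersion, a prior count of 0.5 for scores, and leaving out each mouse. Added after the data were seen were leaving out both libraries that stood apart, the acinar or posterior Hox score as a covariate, and leaving out mitochondrial genes and Lars2. Libraries were compared in pairs by a chi-square of counts over genes with at least 20 reads. The closest value per degree of freedom was 9.36, so no pair was treated as 1 library.

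The tests were checked on simulated counts for this comparison, drawn from the libraries' own means and sizes with 200 genes changed. Each gene was drawn independently, with no library set apart, and the changed genes had at least 1 CPM and lay outside the lists. Variation shared between genes was thus absent, so recovery in the real data may be lower. Of 17959 genes run, edgeR recovered 26.9% of genes changed 2-fold, 91.0% of those changed 4-fold and 97.0% of those changed 8-fold, and 7 of its 150 calls were false. DESeq2 recovered 56.7% of genes changed 2-fold and 98.5% of those changed 4-fold, and made 215 calls, of which 47 were false. With no gene changed, edgeR called 0 and DESeq2 10 of 17934 genes.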

Results

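Proximal colon transcripts were counted in 4 NoDp mice, which carried 8 human gut species, and 4 Dp mice, which carried these and D. piger. Totals were 21.8, 9.24, 25.2 and 15.4 M reads for NoDp replicates 1 to 4, and 6.004, 23.9, 16.6 and 10.8 M reads for Dp replicates 5 to 8. The groups averaged 17.9 ± 7.06 and 14.3 ± 7.70 M reads (SD, n = 4 each; exact two-sided permutation p = 0.543). Dp replicate 5 had the lowest median Spearman correlation with the others across genes (0.907, against 0.959 to 0.984) and 13.5% of its reads on mitochondrial genes, against 3.66% to 8.88% elsewhere.

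The comparison asked how adding D. piger to the community altered host gene expression in the proximal colon. Transcripts of B and plasma cells and of epithelial defence averaged lower with D. piger, but no single gene passed the test over all genes, and neither list was called with an estimated correlation (camera adjusted p = 0.844 and 0.728). The posterior Hox score, a marker of distal gut, had a log2 difference of −0.46 with overlapping groups (exact permutation p = 0.171), and with it as a covariate the median of the B and plasma cell list went from −1.24 to −0.05. Nox1, the NADPH oxidase of the colonic epithelium, averaged 17.4 ± 2.42 CPM without and 9.23 ± 0.923 CPM with D. piger (log2 difference −0.91, SE 0.16). Jchain, which joins IgA and IgM, averaged 403 ± 151 and 155 ± 56.2 CPM (−1.38, SE 0.38). Aqp8, a water channel of surface colonocytes, averaged 288 ± 115 and 126 ± 21.2 CPM (−1.19, SE 0.29). Sqor, the mitochondrial enzyme that begins sulfide oxidation, averaged 547 ± 188 and 624 ± 92.3 CPM (0.19, SE 0.29; 0.03 to 0.34 when single mice were left out).

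edgeR's quasi-likelihood test called 0 of 18115 genes, with a smallest Benjamini-Hochberg adjusted p of 0.830. At an unadjusted p under 0.05 there were 969 genes, 468 higher and 501 lower, where chance gives 906 on average. Over the other ways of splitting the mice into 4 and 4, that number ran from 60 to 3382. limma-voom called 0 genes (smallest adjusted p = 0.153). DESeq2 called 26 genes, 7 higher and 19 lower, of which 7 were named immunoglobulin genes and 7 had no symbol. The 4 mice of one group all lay above those of the other for 4.15% of genes, where chance gives 2.86% on average.

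**Figure D1:**
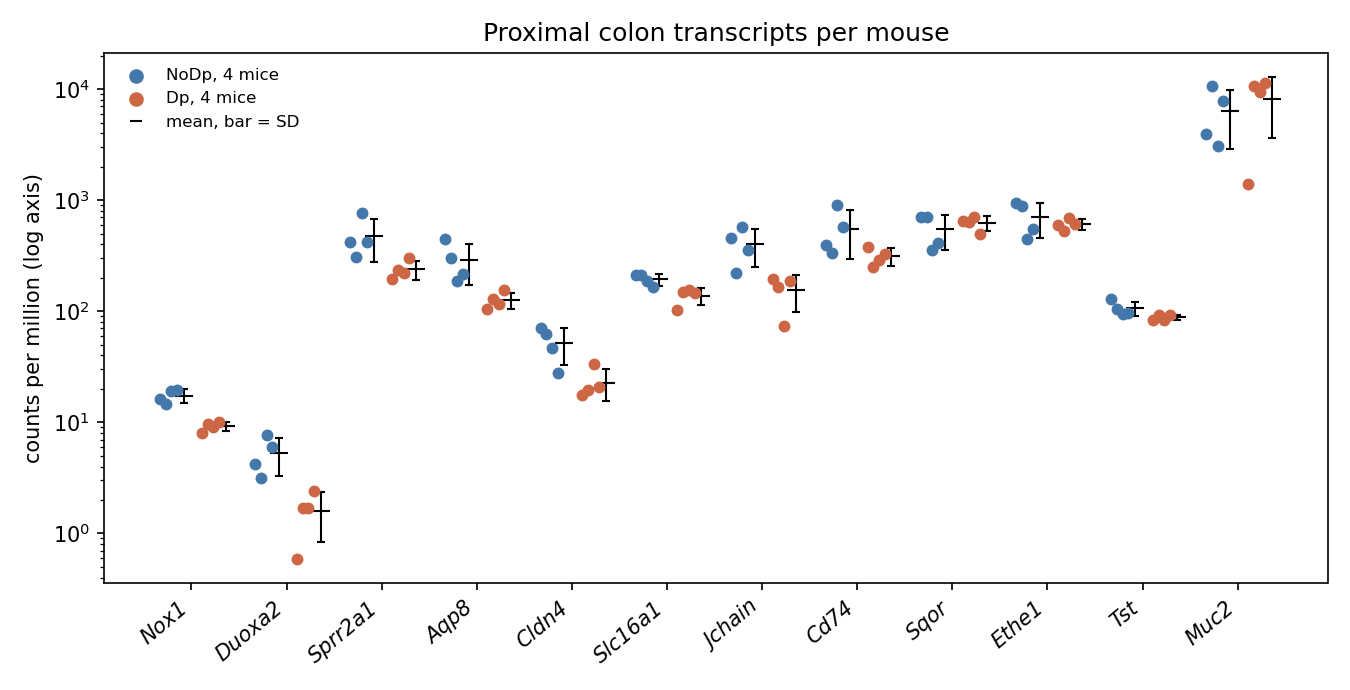
CPM on a log axis for 12 genes in each mouse, with blue points for NoDp and orange points for Dp (4 mice each); black bars are means with SD. Nox1, Duoxa2, Sprr2a1, Aqp8, Slc16a1, Jchain and Tst have groups that do not overlap, while those of Cldn4, Cd74, Sqor, Ethe1 and Muc2 overlap, and no gene passed edgeR's test.

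Among the genes of lowest p, none of which passed, those lower with D. piger were Nox1 and 4 sequences of the immunoglobulin type or without a symbol. Igkv2-137 averaged 22.02 ± 5.20 and 4.64 ± 2.70 CPM (log2 difference −2.19, SE 0.39). Igkv6-13 had a log2 difference of −3.58 (SE 0.74), Ighv7-2 one of −3.22 (SE 0.67), and the unnamed gene ENSMUSG00000076593 one of −2.91 (SE 0.58). In Igkv6-13 the NoDp mean of 43.1 CPM rested on replicate 1 at 118 CPM. Those higher were Gm12018 (1.27, SE 0.23), AI838599 (0.93, SE 0.19), Gm17132 (0.66, SE 0.13), Gm8995 (0.79, SE 0.17) and Arsj, a member of the arylsulfatase family, at 10.3 ± 1.85 and 22.5 ± 6.70 CPM (1.11, SE 0.24). DESeq2 called Nox1, Igkv2-137, Ighv7-2, ENSMUSG00000076593, AI838599, Gm17132 and Arsj, with adjusted p from 0.00151 to 0.0323.

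Antimicrobial and epithelial defence genes fell as a list by camera (adjusted p = 4.7e-06; adjusted p = 0.728 with an estimated correlation). Of its 23 tested members, 20 were lower and 3 higher, with a median log2 difference of −0.50. The score per mouse was 6.67 ± 0.250 and 6.11 ± 0.175, with NoDp replicate 2 (6.34) just below Dp replicate 8 (6.36; n = 4 each; exact permutation p = 0.0571, Benjamini-Hochberg adjusted p = 0.571). No member passed over all genes, and 2 passed adjusted over the list alone, Nox1 and Duoxa2. Duoxa2, the maturation factor of the dual oxidase, averaged 5.26 ± 2.00 and 1.59 ± 0.752 CPM (−1.67, SE 0.38). Sprr2a1, a small proline-rich protein of the epithelium, averaged 477 ± 197 and 238 ± 44.9 CPM (−1.002, SE 0.30), and Sprr1a had a log2 difference of −1.67 (SE 0.52). The log2 differences of the lectins Reg3g (−0.54, SE 0.72) and Reg3b (−0.81, SE 0.88) and of Retnlb (−0.06, SE 0.49) were smaller than their errors, and that of Nos2 was −1.43 (SE 0.70). In the 16 alternatives that kept camera's preset correlation the list was called each time, with a median from −0.57 to −0.29 (highest adjusted p = 0.000877), the median nearest to 0 being that with the posterior Hox score as a covariate. Epithelial marker scores beside these were 8.98 ± 0.223 in NoDp and 8.72 ± 0.293 in Dp mice (log2 CPM, n = 4 each; exact permutation p = 0.257).

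B and plasma cell genes fell as a list by camera, with 19 of 20 members lower and a median of −1.24 (adjusted p = 1.6e-11; adjusted p = 0.844 with an estimated correlation). None passed over all genes or over the list alone. Tnfrsf17, a receptor of plasma cells, had a log2 difference of −1.80 (SE 0.44). Mzb1, a plasma cell chaperone, averaged 19.5 ± 11.8 and 6.53 ± 2.79 CPM (−1.62, SE 0.48), and Cd79a, part of the B cell receptor, 48.8 ± 40.9 and 15.9 ± 4.59 CPM (−1.63, SE 0.58). Cd79a stood at 18.8 and 15.1 CPM in NoDp replicates 1 and 2, within the Dp range of 11.3 to 22.04 CPM, and its log2 difference was −0.96 without NoDp replicate 3. The list score per mouse was 2.80, 2.49, 4.80 and 4.24 in NoDp replicates 1 to 4 and 3.03, 2.69, 2.30 and 2.91 in Dp replicates 5 to 8, so that the groups overlapped (exact permutation p = 0.286). Posterior Hox transcripts were not called as a list (camera adjusted p = 0.323), and the difference of their score went from −0.46 to −0.20 without NoDp replicate 3. That score was 4.46 in NoDp replicate 3 and 2.96 to 3.66 in the other 7 mice, and Hoxb13 stood at 366 CPM in NoDp replicate 3, 73.3 CPM in NoDp replicate 4 and 1.37 to 32.8 CPM in the rest. With that score as a covariate the list's median was −0.05 and its call ended (adjusted p = 0.241 by camera, the highest over 16 alternatives at the preset correlation, the lowest being 8.9e-26). Without NoDp replicate 3 the median was −0.66, and without both that library and Dp replicate 5 it was −0.80.

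MHC class II genes fell as a list, with 14 of 14 members lower and a median of −0.62 (camera adjusted p = 4.7e-06; adjusted p = 0.844 with an estimated correlation). Cd74, the invariant chain, averaged 556 ± 259 and 313 ± 56.8 CPM (−0.83, SE 0.33), H2-Eb2 had a log2 difference of −1.21 (SE 0.48), H2-DMb2 one of −0.78 (SE 0.33) and H2-DMb1 one of −0.57 (SE 0.24). With the posterior Hox score as a covariate the median was −0.16 and the call ended (adjusted p = 0.197 by camera, the highest over 16 alternatives at the preset correlation, the lowest being 2.7e-10). Without NoDp replicate 3 the MHC class II median was −0.32, and the scores per mouse, 4.62 ± 0.569 and 4.11 ± 0.401, overlapped (n = 4 each; exact permutation p = 0.200). T cell and innate lymphoid genes fell as a list (16 of 22 lower, median −0.21; camera adjusted p = 0.0250; adjusted p = 0.844 with an estimated correlation), with Cd6 at −1.47 (SE 0.46) and Cd4 at −1.04 (SE 0.37). That call was lost without any one of NoDp replicates 3 and 4 and Dp replicates 6, 7 and 8 (medians from −0.28 to −0.097, highest adjusted p = 0.159), and with the Hox covariate (median −0.03, adjusted p = 0.775), while the median was −0.37 without NoDp replicate 2 and −0.41 without Dp replicate 5. Interferon-stimulated genes fell as a list (29 of 36 lower, median −0.28; camera adjusted p = 0.00940; adjusted p = 0.844 with an estimated correlation), with Oasl1 at −1.12 (SE 0.33) and Oas3 at −0.90 (SE 0.35). Without NoDp replicate 3 their median was 0.08 and the call ended, and with the Hox covariate the list was called higher (median 0.23, adjusted p = 0.00300); over 16 alternatives at the preset correlation the adjusted p ran from 9.2e-06 to 0.714. Inflammatory cytokines and chemokines were not called (7 of 10 lower; adjusted p = 0.219 by camera); Tgfb1 had a log2 difference of −0.75 (SE 0.25) and Il18 one of −0.55 (SE 0.25).

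**Figure D2:**
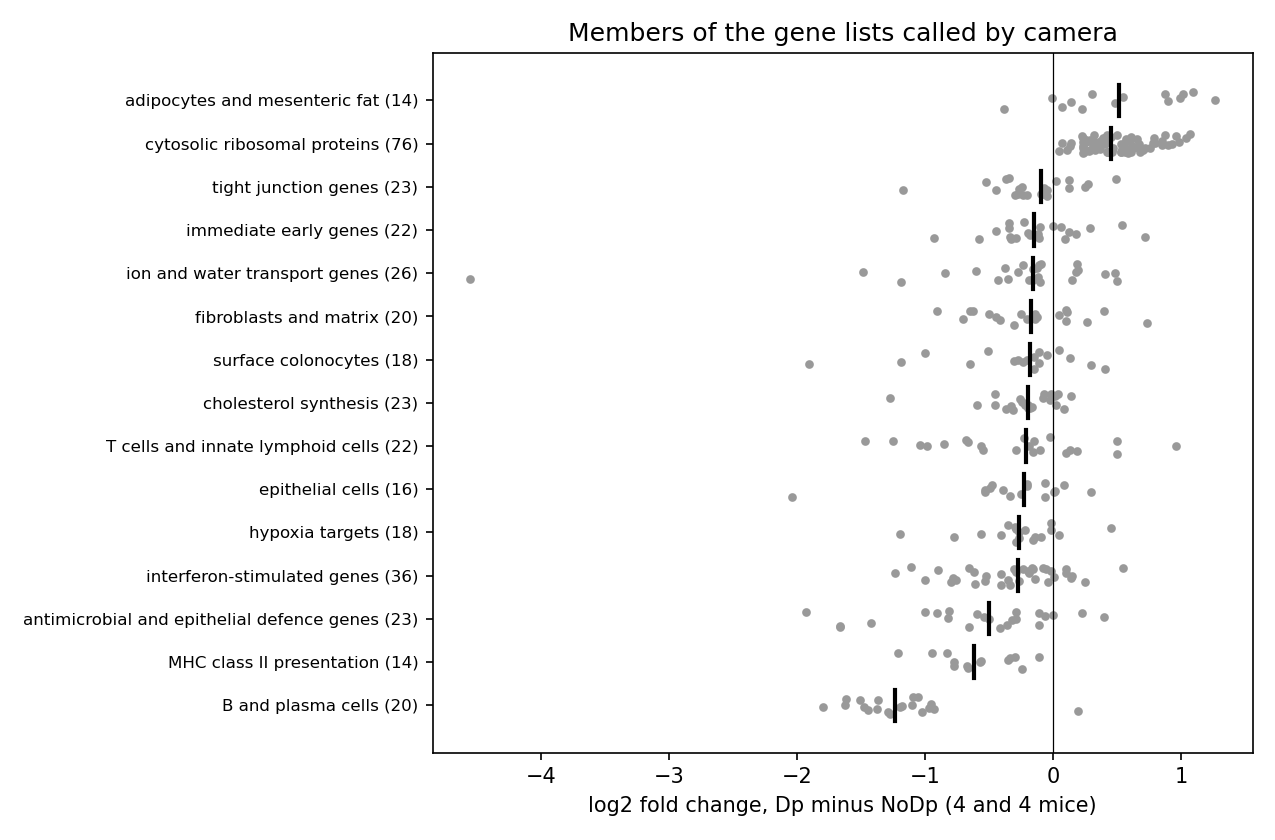
Log2 fold change of each tested member (grey points) of the 15 gene lists called by camera at the preset correlation, with the list median as a black line and the number of members in parentheses; negative values are lower with D. piger. B and plasma cell genes have the lowest median (−1.24), all 76 ribosomal protein genes lie above 0, and no list was called with an estimated correlation.

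The sulfide oxidation list was not called (7 of 9 members lower, median −0.22; adjusted p = 0.381 by camera). Ethe1, the persulfide dioxygenase, averaged 707 ± 246 and 605 ± 67.3 CPM (−0.22, SE 0.29; −0.39 to −0.05 when single mice were left out), and Tst, or rhodanese, 106 ± 15.8 and 88.1 ± 5.02 CPM (−0.27, SE 0.15). Suox (−0.05, SE 0.23) and Mpst (−0.48, SE 0.49, −0.76 to −0.14 when single mice were left out) did not pass either. No call was made for cysteine, taurine and glutathione synthesis (8 of 13 lower, adjusted p = 0.653 by camera; Cbs −0.51, SE 0.26), sulfate uptake and sulfation (10 of 18 lower, adjusted p = 0.831; Sult1c2 0.63, SE 0.36), or glycosaminoglycan breakdown (10 of 15 lower, adjusted p = 0.187; Hyal1 0.41, SE 0.16). The sulfate transporter Slc26a2 averaged 825 ± 218 and 596 ± 220 CPM (−0.47, SE 0.35, −0.62 to −0.24 when single mice were left out). For sulfate uptake and sulfation the median was −0.09 but the mean and camera pointed up. Complex IV subunits, the respiratory complex that sulfide inhibits, were higher in 12 of 13 (adjusted p = 0.275 by camera) and complex I subunits in 30 of 37 (adjusted p = 0.187). Their leading members were high in Dp replicate 5, with Cox6c at 1181 CPM against 215 to 238 CPM in the other Dp mice, and Ndufa4 at 501 CPM against 134 to 165 CPM. NRF2 antioxidant targets were lower in 15 of 25 (adjusted p = 0.548 by camera), with G6pdx at −0.32 (SE 0.15) and Hmox1 at 0.01 (SE 0.26). Hypoxia targets fell as a list (16 of 18 lower, median −0.27; camera adjusted p = 0.00167; adjusted p = 0.844 with an estimated correlation). Egln3, a prolyl hydroxylase, averaged 94.1 ± 51.8 and 41.0 ± 6.43 CPM (−1.20, SE 0.33), with NoDp replicate 3 at 171 CPM, and Egln1 had a log2 difference of −0.35 (SE 0.17). With the posterior Hox score as a covariate the hypoxia median was −0.15 and its call ended (adjusted p = 0.0661 by camera, the highest over 16 alternatives at the preset correlation, the lowest being 0.000299), and without both NoDp replicate 3 and Dp replicate 5 the median was −0.15 as well. The hypoxia score per mouse was 6.44 ± 0.189 and 6.16 ± 0.072 (n = 4 each; exact permutation p = 0.0286, Benjamini-Hochberg adjusted p = 0.571).

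Among epithelial functions, Slc16a1, the butyrate and lactate transporter, averaged 194 ± 23.6 and 138 ± 23.3 CPM (−0.50, SE 0.19) with groups that did not overlap. Slc5a8 averaged 118 ± 45.8 and 87.1 ± 32.5 CPM (−0.43, SE 0.36, −0.60 to −0.17 when single mice were left out). Their list of short-chain fatty acid genes was not called (12 of 19 lower, adjusted p = 0.323 by camera). PPAR-alpha targets were higher in 17 of 24 (adjusted p = 0.0745; Fabp1 1.34, SE 0.54), goblet cell and mucus genes lower in 12 of 20 (adjusted p = 0.381; Best2 −1.48, SE 0.64, or −0.55 without NoDp replicate 3 at 48.9 CPM), unfolded protein response genes lower in 17 of 25 (adjusted p = 0.0717; Creld2 −0.42, SE 0.17) and cell cycle genes lower in 16 of 30 (adjusted p = 0.548; Tyms 0.24, SE 0.13), all uncalled by camera. Muc2, the main secreted mucin, had a log2 difference of 0.37 (SE 0.65, 0.14 to 0.73 when single mice were left out). It stood at 1392 CPM in Dp replicate 5, against 9502 to 11337 CPM in the other Dp mice. Gcg, which encodes glucagon-like peptides, had a log2 difference of 0.07 (SE 0.29).

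Tight junction genes fell as a list (17 of 23 lower, median −0.10; camera adjusted p = 0.0440; adjusted p = 0.844 with an estimated correlation). Cldn4, a claudin, averaged 51.8 ± 18.9 and 22.8 ± 7.17 CPM (−1.18, SE 0.31), while Jam2 had a log2 difference of 0.49 (SE 0.18), Ocln one of −0.07 (SE 0.18) and Tjp1 one of −0.07 (SE 0.36). The call was lost without NoDp replicate 1 (median −0.19, adjusted p = 0.0893), NoDp replicate 2 (−0.068, 0.116) or Dp replicate 5 (0.012, 0.816), and with library-size scaling (−0.10, 0.0567) or the smooth muscle covariate (−0.069, 0.0594), while the median was −0.18, −0.19 and −0.18 without Dp replicates 6, 7 and 8. Ion and water transport genes fell as a list (19 of 26 lower, median −0.16; camera adjusted p = 0.0355; adjusted p = 0.844 with an estimated correlation), including Aqp8, Slc26a3 (−0.27, SE 0.23) and the proton pump Atp12a (−4.56, SE 1.66), which stood at 671 CPM in NoDp replicate 3 and 162 CPM in NoDp replicate 4. That call was lost without NoDp replicate 4 (median −0.12, adjusted p = 0.0587) or Dp replicate 5 (−0.11, 0.602), and the median was −0.28 without Dp replicate 8. Cholesterol synthesis genes fell as a list (18 of 23 lower, median −0.19; camera adjusted p = 0.00940; adjusted p = 0.844 with an estimated correlation), with Mvk at −0.46 (SE 0.19) and Mvd at −0.59 (SE 0.33). The call was lost without NoDp replicate 3 (median −0.078, adjusted p = 0.137) or Dp replicate 5 (−0.059, 0.602), and with the Hox covariate (median −0.0034, adjusted p = 0.634), and the median was −0.34 without Dp replicate 6.

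Markers of tissue composition differed between single mice as well as between groups. Epithelial markers (12 of 16 lower, median −0.23, adjusted p = 0.0368), surface colonocyte markers (14 of 18, −0.18, 0.0381) and fibroblast and matrix genes (13 of 20, −0.18, 0.0262) fell as lists by camera; each had adjusted p = 0.844 with an estimated correlation. Aqp8 alone passed adjusted over the surface colonocyte list. Cdx1 had a log2 difference of −0.50 (SE 0.25), Tmprss2 one of −0.54 (SE 0.27), Sprr2a2, which is so similar to Sprr2a1 that reads cannot be assigned with certainty, one of −1.005 (SE 0.32), Col1a1 one of −0.91 (SE 0.33) and Col3a1 one of −0.71 (SE 0.26). Adipocyte genes rose as a list (12 of 14 higher, median 0.51; camera adjusted p = 0.0250; adjusted p = 0.844 with an estimated correlation), with Cidec at 1.09 (SE 0.67) and Cfd at 1.01 (SE 0.65), which were 0.17 and 0.15 without Dp replicate 5. Immediate early genes fell as a list (15 of 22 lower, median −0.15; camera adjusted p = 0.0437; adjusted p = 0.844 with an estimated correlation), with Klf2 at −0.58 (SE 0.35) and Atf3 at −0.35 (SE 0.23). Cytosolic ribosomal protein genes rose as a list (76 of 76 higher, median 0.45; camera adjusted p = 0.00167; adjusted p = 0.896 with an estimated correlation), with Rpl30 at 0.85 (SE 0.50) and Rps27 at 1.04 (SE 0.63).

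Single mice decided several of these. Without Dp replicate 5, whose ribosomal score was 10.03 against 8.11 to 8.15 in the other Dp mice, the ribosomal list was called lower with a median of −0.28. In that fit NoDp replicate 1 stood at 8.92, against 8.08 to 8.25 in NoDp replicates 2 to 4. The lower call may therefore rest on NoDp replicate 1, and a fit without both mice was not run. The adipocyte call was lost without NoDp replicate 3 (median 0.22) or Dp replicate 5 (0.042; highest adjusted p = 0.691). The epithelial call was lost without NoDp replicate 1 (median −0.23, as with all mice), NoDp replicate 2 (−0.15) or Dp replicate 5 (−0.088; highest adjusted p = 0.540). The surface colonocyte call was lost while the median stayed close or grew, without NoDp replicate 1 (−0.20), NoDp replicate 2 (−0.16), Dp replicate 5 (−0.15) or Dp replicate 8 (−0.30; highest adjusted p = 0.278). The fibroblast call was lost without NoDp replicate 2 (−0.14), NoDp replicate 3 (−0.15) or Dp replicate 8 (−0.29; highest adjusted p = 0.0994), and the immediate early call without NoDp replicate 2 (−0.18), NoDp replicate 4 (−0.097), Dp replicate 5 (−0.069) or Dp replicate 6 (0.0027; highest adjusted p = 0.639). Medians also moved where calls held, to 0.70 for ribosomal, 0.88 for adipocyte and −0.37 for fibroblast genes without NoDp replicate 1, −0.28 for fibroblast genes without Dp replicate 7, −0.30 for surface colonocytes and −0.098 for immediate early genes without NoDp replicate 3, and −0.45 for immediate early genes without Dp replicate 8. Pancreatic acinar genes were present at very different levels: Pnlip, pancreatic lipase, stood at 4.13, 105, 1.00 and 5525 CPM in NoDp replicates 1 to 4 and at 101, 1290, 78.6 and 1279 CPM in Dp replicates 5 to 8. All 17 acinar genes had negative log2 differences (median −1.01), while camera and the per-mouse score (5.43 ± 4.36 and 7.61 ± 2.03 log2 CPM, n = 4 each; exact permutation p = 0.400) pointed up. With the posterior Hox covariate the calls of fibroblast (median −0.073, adjusted p = 0.149), immediate early (−0.010, 0.344) and adipocyte genes (−0.033, 0.187) ended, while the surface colonocyte median went to −0.44 (adjusted p = 3.6e-07). The immediate early call also ended with the smooth muscle covariate, at the same median of −0.15 (adjusted p = 0.0998), and the interferon-stimulated call with the acinar covariate (median −0.13, adjusted p = 0.189), a score in which Zg16 is also a goblet cell gene. Without both NoDp replicate 3 and Dp replicate 5, the tight junction (0.902), ion and water transport (0.647), cholesterol (0.415), epithelial (0.415), fibroblast (0.0973), immediate early (0.749), interferon-stimulated (0.714) and adipocyte (0.0636) calls ended. The smooth muscle score was 7.73 ± 0.156 and 7.68 ± 0.271 (n = 4 each; exact permutation p = 0.800), and its list had a median of −0.07 with a mean of 0.0013. Of macrophage genes 10 of 19 were higher with a median of 0.04, while camera pointed down (adjusted p = 0.404). The remaining cell type and dissection lists were not called by camera (adjusted p from 0.0717 to 0.996).

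**Figure D3:**
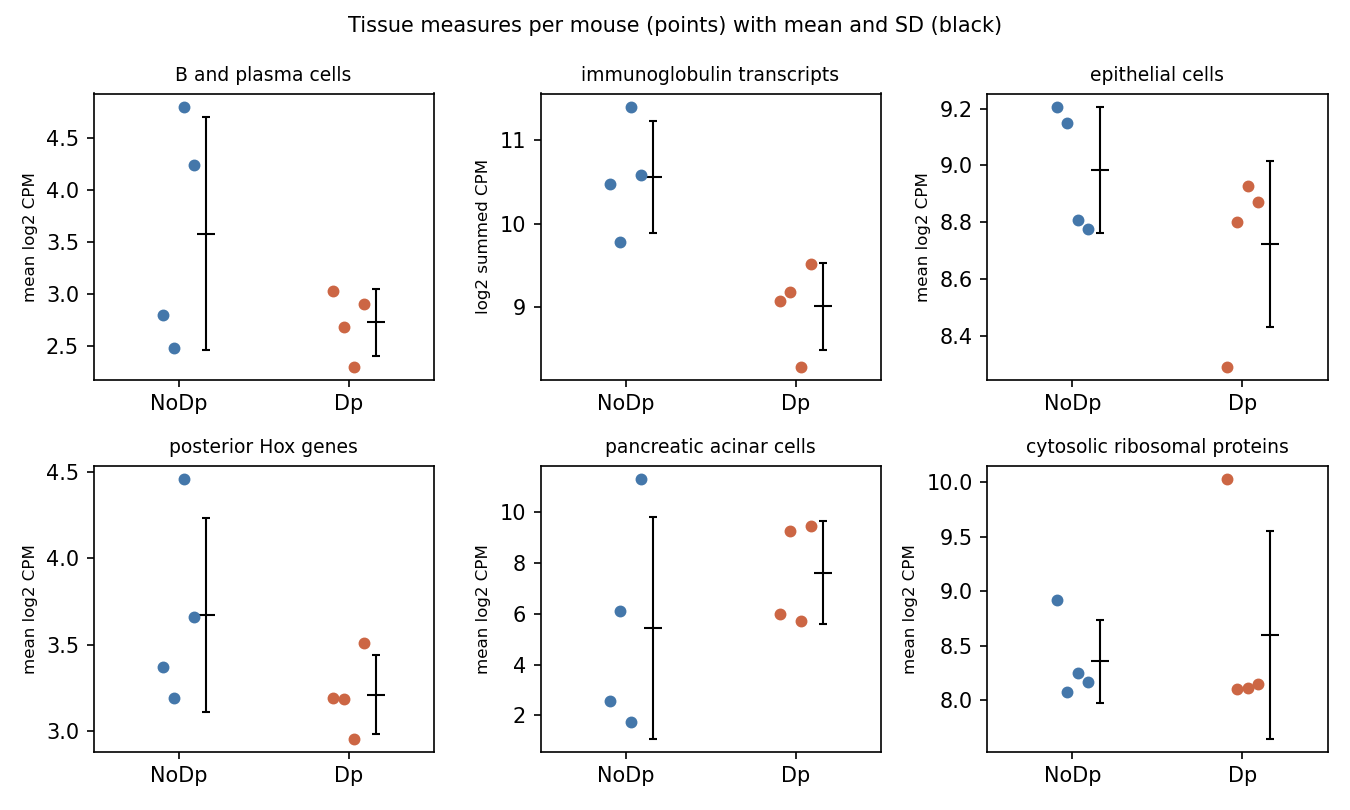
Mean log2 CPM of 5 gene lists and the log2 summed CPM of 62 immunoglobulin genes for each mouse (blue NoDp, orange Dp, 4 each; black, mean with SD; axes do not start at 0). The immunoglobulin sum, chosen after its groups were seen not to overlap, separates the groups. The other measures overlap, with NoDp replicate 3 highest for posterior Hox genes and Dp replicate 5 highest for ribosomal proteins.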

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

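The tests of immunoglobulin transcripts, of Nox1 and its companions and of Dp replicate 5 were chosen after these results were seen. In 206 groups of 4 values, 23 had a mouse set apart from the other 3, where chance gives 10.3; 11 of the 23 were Dp replicate 5. The number given with each is its gap to the nearest mouse as a share of the group's range.

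Dp replicate 5 lay apart from the other Dp mice with higher CPM of Cox6c (0.976), Ndufa4 (0.916), Fabp1 (4.29 against 1.08 to 1.39 CPM, 0.905), H2-DMb2 (18.7 against 9.86 to 11.2 CPM, 0.848), H2-DMb1 (12.9 against 9.17 to 9.39 CPM, 0.941), Cfd (914 against 142 to 250 CPM, 0.861), Rpl30 (809 against 188 to 206 CPM, 0.971) and Rps27 (892 against 142 to 172 CPM, 0.960), and with a higher ribosomal protein score (0.977). It had lower CPM of Ocln (61.2 against 93.3 to 99.6 CPM, 0.836) and Tjp1 (46.8 against 143 to 152 CPM, 0.908).

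NoDp replicate 3 was high for Egln3 (0.867), Mvd (56.0 against 25.3 to 30.1 CPM, 0.845) and Gsdmc3 (381 against 122 to 152 CPM, 0.884). NoDp replicate 1 was high for Igkv6-13 (118 against 14.2 to 20.9 CPM, 0.935), Rps27 (259 against 123 to 146 CPM, 0.831) and the share of reads on Lars2 (0.919% against 0.132% to 0.258%, 0.840). NoDp replicate 4 was high for Hmox1 (9.40 against 5.57 to 6.19 CPM, 0.839), Pnlip (0.981) and summed acinar transcripts (45665 against 269 to 988 CPM, 0.984; Zg16, also a goblet cell gene, left out). Dp replicate 7 was high for Igkv6-13 (5.52 against 2.73 to 2.97 CPM, 0.915) and the surface colonocyte score (8.501 against 8.17 to 8.22, 0.855), and Dp replicate 8 for Atp12a (25.5 against 2.99 to 4.13 CPM, 0.949).

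The first pattern is Dp replicate 5 itself. Its depth of 6.004 M reads does not account for it: with every library thinned to its total, its median Spearman correlation was still 0.906, against 0.954 to 0.981 for the others. Its scores were the lowest for epithelial cells (8.29 against 8.78 to 9.20) and the highest for macrophages (4.68 against 3.17 to 4.18), neutrophils (2.91 against 1.81 to 2.26), red blood cells (5.33 against 3.17 to 4.29) and adipocytes (7.42 against 4.54 to 6.85), while the mean of its neuron and muscle scores lay −0.459 log2 from the median of the others, below their range of −0.293 to 0.279. A smaller share of epithelium would by itself raise the other types alike, which these scores do not show. The scores were not adjusted for transcript length, though, and long genes were lower in this library, so they cannot decide. Less epithelium and more blood, immune or fat tissue both stay open. Loss of long transcripts is also a candidate explanation, since the longest quintile of genes was lower than the shortest by −1.32 log2. That difference was −0.722 in NoDp replicate 1, the next lowest, and 0.013 to 0.176 in the remaining libraries. Ribosomal protein genes were 1.89 log2 above the other libraries. That still exceeded the central 95% of 10000 random lists matched on length and level (upper end 0.741). Those lists drew genes singly, whereas ribosomal protein genes varied together (estimated correlation 0.983). The excess therefore cannot show a cause beyond loss of long transcripts. No biological explanation beyond the share of epithelium was tested.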

How the results depend on the processing

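The covariates for acinar and posterior Hox scores, the fits without both libraries that stood apart, and the fits without mitochondrial genes and Lars2 were chosen after the data were seen. edgeR called 0 genes under every setting run with it, including all 8 fits that left out a mouse, and limma-voom called 0 (969 genes at an unadjusted p under 0.05 by edgeR), whereas DESeq2 called 26 (7 higher, 19 lower). On simulated counts DESeq2 made more false calls but also recovered more of the 2-fold changes (56.7%, against 26.9% by edgeR). Camera called 15 lists, 11 to 19 when a mouse was left out, 0 with an estimated correlation, 0 by fry and 0 by fry in either direction; the other settings gave 13 to 18. The antimicrobial and defence list kept its call under all 16 alternatives at the preset correlation, and the B and plasma cell, MHC class II and hypoxia lists lost theirs with the posterior Hox covariate alone (medians −0.050, −0.16 and −0.15). No paired analysis was possible because the groups share no replicate numbers. In the 35 ways of splitting the 8 mice into 4 and 4, edgeR called 0 genes in all 35, so that the real count of 0 and the highest other of 0 are equal. As many lists as the real 15 came in 23 of the 35 splits (highest other 26) and as many DESeq2 genes as the real 26 in 7 of 35 (highest other 96), so chance cannot be excluded for either count. The split with 96 genes and 26 lists set NoDp replicates 1 and 2 and Dp replicates 5 and 7 against the rest. A structure of the samples other than the groups may lie behind it, but this was not tested. At this depth and spread, edgeR recovered 26.9% of 2-fold changes simulated without variation shared between genes.

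Reversed values concerned genes that did not pass and lists led by single mice; unless stated, the cause was not tested. When single mice were left out, log2 differences ranged for Suox from −0.22 to 0.085, Retnlb −0.35 to 0.40, Reg3g −0.92 to 0.34, Reg3b −1.47 to 0.068, Ocln −0.14 to 0.061, Tjp1 −0.23 to 0.19, Hmox1 −0.13 to 0.22, Gcg −0.15 to 0.26, Cox6c −0.14 to 1.22, Rps27 −0.11 to 1.34 and Pnlip −1.53 to 4.24. Medians ranged from −0.38 to 0.079 for interferon-stimulated genes and −0.28 to 0.70 for ribosomal proteins, and score differences from −0.17 to 0.027 for smooth muscle and −0.23 to 0.43 for ribosomal proteins. Without both libraries that stood apart, values were Slc5a8 0.075, Ocln 0.061, Tjp1 0.29, Hmox1 −0.16, Gcg −0.11, Cox6c −0.26, Cidec −0.12, Cfd −0.12, Rpl30 −0.042 and Rps27 −0.20, and list medians were 0.067 for cholesterol synthesis, −0.018 for interferon-stimulated genes, whose camera direction turned, −0.20 for adipocytes and −0.31 for ribosomal proteins. With the posterior Hox covariate they were Sqor −0.15, Slc5a8 0.0045, Tjp1 0.025, Hmox1 −0.0019, Gcg −0.13 and Pnlip 0.34, with medians of 0.23 for interferon-stimulated genes and −0.033 for adipocytes. With the acinar covariate they were Hmox1 −0.061, Gcg −0.063 and Pnlip 0.37, and with the smooth muscle covariate Hmox1 −0.0081 and Pnlip 3.24. With limma-voom they were Suox 0.15, Ocln 0.020, Tjp1 0.12, Hmox1 −0.23 and Gcg −0.020, and with 1 surrogate variable Tjp1 0.14 and Hmox1 −0.084. Hmox1 was −0.018 by library size only, −0.0083 by DESeq2 and −0.0059 with no filter.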

Other observations

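The tests of immunoglobulin transcripts and of Nox1, Duoxa2, Aqp8 and the Gsdmc genes were chosen after the values were seen, on the genes that showed the pattern, so both patterns are hypotheses. The Gsdmc genes, a family of gasdermins expressed in colonic epithelium, had lower levels in each Dp mouse than in any NoDp mouse. Gsdmc2 averaged 413 ± 201 and 186 ± 51.1 CPM (log2 difference −1.16, SE 0.35), Gsdmc4 518 ± 268 and 204 ± 52.1 CPM (−1.35, SE 0.36), Gsdmc −1.34 (SE 0.33) and Gsdmc3 −1.36 (SE 0.38). None passed edgeR's test (adjusted p = 0.830), and since their sequences are alike, reads may be shared among them, so the 4 values are not independent. With the posterior Hox score as a covariate the log2 differences were −0.83 for Gsdmc, −0.67 for Gsdmc2, −0.65 for Gsdmc3 and −0.79 for Gsdmc4.

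Clock genes were not called as a list (7 of 18 higher, 11 lower; adjusted p = 0.996 by camera), and members went both ways. Hlf averaged 18.0 ± 2.05 and 26.8 ± 4.54 CPM (0.57, SE 0.16) and Nr1d2 87.9 ± 10.4 and 123 ± 24.1 CPM (0.48, SE 0.18), while Arntl averaged 10.7 ± 1.89 and 7.45 ± 1.26 CPM (−0.51, SE 0.20). None of the 3 passed, and times of death were not given.

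Immunoglobulin transcripts form the second pattern. Of 62 named immunoglobulin genes, 59 were lower with D. piger (median −1.45), and 11 had groups that did not overlap. Igkc averaged 1024 ± 334 and 352 ± 112 CPM, and the summed level was 1639 ± 775 and 538 ± 173 CPM (SD, n = 4 each, log2 difference −1.55). The sum was chosen after its groups were seen not to overlap, so a permutation test of it decides nothing. The difference was −1.20 with the follicular B cell score (9 genes) as a covariate and −0.968 with the posterior Hox score. The latter covariate also ended the call of the B and plasma cell list, which holds markers of both cell types. Scored apart after the data were seen, 6 plasma cell genes averaged 4.79 to 5.48 log2 CPM in NoDp mice and 3.75 to 4.49 in Dp mice. The genes were Jchain, Mzb1, Tnfrsf17, Prdm1, Xbp1 and Sdc1. Since Jchain, Mzb1 and Tnfrsf17 were already known to be lower, this separation is no independent support. The follicular score overlapped, at 1.86 to 4.51 and 1.98 to 2.57. The plasma cell score was not fitted with the Hox covariate. In NoDp replicates 1 and 2 the follicular score was 2.02 and 1.86, against 1.98 to 2.57 in Dp mice. Their Hox score was 3.37 and 3.19, against 2.96 to 3.51. Their log2 immunoglobulin sums, 10.5 and 9.77, still lay above those of every Dp mouse (8.27 to 9.51). Neither score lay above the Dp range in those mice. The higher sums there followed from how the sum was chosen, so these values cannot exclude more lymphoid follicle tissue or more distal colon. Either may still contribute in the NoDp pieces. Chance stays open, as do, untested, an effect of D. piger on plasma cells and of cages.

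In the third pattern, the mean log2 CPM of Nox1, Duoxa2, Aqp8 and the 4 Gsdmc genes was 6.56 ± 0.425 in NoDp and 5.35 ± 0.178 in Dp mice (SD, n = 4 each; difference −1.22). Each gene was picked with groups that do not overlap, so a permutation test of their mean decides nothing. The epithelial score differed by −0.26, and by −0.91 between the lowest Dp and the highest NoDp mouse, both smaller than the −1.22 of these genes. The difference of these genes was −1.29 with that score as a covariate. Picking genes for their separation can enlarge their difference, though, so this comparison cannot exclude less epithelium in the Dp pieces. With the posterior Hox score as a covariate the difference was −0.908. That score was 3.37 and 3.19 in NoDp replicates 1 and 2, within the 2.96 to 3.51 of Dp mice. The mean of these genes was 6.60 and 6.20 there, against 5.21 to 5.59 in Dp mice. Because each gene was picked for its separation, that mean had to lie above the Dp range. These values therefore cannot exclude more distal colon in the NoDp pieces, as the whole cause or as a part. A response of the epithelium to D. piger may be involved but was not tested, and cages were not given.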
